A study of Oryza sativa with 12 samples.

How the data were processed

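Leaf RNA of rice was measured on 12 one-colour arrays of a custom Agilent design with 4 arrays to a slide. Per the labels, total RNA was labelled with Cy3, and each array holds 1 plant type at 1 time. A plant type is a genotype at a growth stage. The times were before water was withheld, after 8 days of soil moisture stress and after a further 2 days of recovery, with 4 arrays each. Nivara and rufipogan are labelled wild and N22 a cultivar; N22 was read from the sample titles. No plant type has a second array at any time, so plant types stood in as the replicates of a time, and nothing in the labels says how many plants were pooled. The p-values between times therefore measure how the changes differ between these plant types, and not between repeats of 1 type. In contrasts between plant types the times stand in as replicates, so those p-values rest on no replicate of a stage or genotype.

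The scanner values are spot intensity as the authors deposited it, made with Agilent Feature Extraction 10.7.3.1 per the file headers. The processed signal has background subtracted and spatial and multiplicative trends removed, with a surrogate value in place of a signal not above background. The authors also deposited a matrix of log2 values. On each array these equal the log2 processed signal minus 1 constant to within 0.01 for 42134 to 42200 probes, and their medians run from −3.23 to −1.90. Their scale, direction and centring follow from that match; the software of that step is not given in the sources used here. Annotation in the files refers to rice genome build 5 of IRGSP, and coordinates below are those of the probes in that build.

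Each array holds 42429 gene probes. The 480 spots of random or artificial sequence were left out, as were 508 probes with an outlier flag. Spots of 1 probe were averaged, and values were taken as log2 of that signal minus the log2 of the array's 75th percentile. Probes had to be well above background on at least 3 of the 12 arrays, which left 35430 probes for 23371 genes. A locus came from the accession list for 34947 probes and from the probe design for 6036; 1021 probes match several loci and 425 none, and neither was given a name. The array files list 3435 RefSeq accessions, of which the RefSeq table used here held 0, so descriptions are those in the array files and symbols those of the gene lists. For a gene with several probes the probe with the brightest mean was used. Probes past the threshold disagreed in sign for 1 gene in the stage comparison, 1 in the comparison of rufipogan with nivara, and 918 in that of N22.

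Values were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, in an additive model of time and plant type over all 12 arrays. The residual had 5 degrees of freedom and the prior 3.09. The plant type is a block because before and after arrays come from the same genotype and stage per the labels; that they come from the same plants is not stated. Array correlations were checked against the pairing. Among the 10 arrays other than N22 they ran from 0.812 to 0.977 within a plant type and from 0.76 to 0.934 between types, and the 2 N22 arrays correlated at 0.936. Nivara grain-filling at stress was closer to rufipogan vegetative at stress (0.851) than to its own type before (0.812) or at recovery (0.818). Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Contrasts between times rested on 4 pairs (stress against before) or 3 pairs (both contrasts with recovery). Because 1 fit held all 12 arrays, the N22 pair before and at stress also shifted the estimates of both contrasts with recovery. Contrasts between plants used 3 arrays against 3, or the 2 N22 arrays against the wild grain-filling plants. The 2 tests of a different stress response were fitted to the 4 log2 ratios, 1 ratio against 3, with the lone ratio assumed to vary like the others.

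The design, the alternatives, 29 gene lists and the rule for naming genes were fixed before the data were examined. The 27 lists with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the lists, and again with an estimated correlation and with fry. Of the fixed list members, 10 were left out because the array's description did not match a keyword set for the family, and 1 because no probe had its locus alone. The keywords missed some names of the same family, such as DRE-binding protein 1A for DREB1A. NCED5 of the abscisic acid list, PRR59 of the clock list and Hd3a of the flowering time list were also left out. The root-enriched and the senescence lists had fewer than 5 measured genes and are described by their members alone. For a single pair of arrays a list's median was placed among those of 10000 random lists of the same size and signal level, which describes those arrays and is no test. Named genes are the 8 highest and 8 lowest log2 changes past the threshold in the stress comparison and the 6 highest and 6 lowest elsewhere, with all pairs in 1 direction and a protein description. Where too few passed, the smallest unadjusted p under 0.05 filled the places. The 3 members of a list with the smallest p could also be named, with 5 for the late embryogenesis abundant, abscisic acid and drought transcription factor lists and the members for flowering time in the stage comparison, of which 1 is not reported here. The members behind some counts of 5 or fewer in the stage comparison, and the 5 probes called on all 12 arrays, were named after their values were seen.

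A gene well above background on 0 arrays of 1 group has only a bound there. Its fold is then given as at least the bright group's mean over the dim group's, taking for each dim array the higher of the probe's own signal and the lowest signal well above background. The same is done for some genes well above background on only part of a group's arrays, and where such a gene's log2 change is given it rests partly on near-background signal. Where arrays of the brighter group were also near background, the value is no lower bound and is not given as one. The number of arrays limits the precision, and so does signal near background.

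The fits were tested on simulated data of 35430 probes, with 50 probes changed at each of 4 sizes. In the stress comparison 0% of the changes of log2 1 were recovered, 8% at 2, 62% at 4 and 82% at 6, with 4 false calls. In the stage comparison the shares were 0%, 4%, 64% and 72%, with 1 false call. For the different response of N22, 0% was recovered at every size up to 6. A simulated shift of the late embryogenesis list by log2 1 was not called (camera adjusted p = 0.217), while shifts of 2 and 3 were, and 0 of the 26 other lists were called. The simulated noise was independent between genes, whereas the estimated correlation within this list was 0.469 in the real data. The simulation therefore does not show how often lists are called falsely in the real data.

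Alternatives were quantile normalization, normexp background correction (offset 50), the deposited matrix, 2 other filters, an intensity trend with robust variances, the slide as a block, 1 probe per gene, only the arrays compared, no plant block or a random one, and leaving out each plant type or array. Leaving out the 2 N22 arrays, and for the gene lists leaving out nivara grain-filling or adding the slide as a block, were chosen after seeing the data. Slide 1 held the 4 nivara arrays, slide 2 rufipogan before stress and at 8 days of stress, and slide 3 rufipogan at recovery and N22. Scan sessions coincide with slides. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.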

Results

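Gene expression was measured in rice leaves on 12 one-colour arrays, with 4 arrays before stress, 4 after 8 days of soil moisture stress and 4 after 2 days of recovery. The series asks how water stress acts in different rice genotypes at the vegetative and grain-filling stages. The plants were nivara and rufipogan (spelled as in the labels), wild relatives of cultivated rice, and N22, a cultivar known for drought tolerance. Before stress and at 8 days the 4 arrays were nivara grain-filling, rufipogan vegetative, rufipogan grain-filling and N22 grain-filling. At recovery a vegetative nivara plant took the place of N22. No plant type had a second array at any time, and whether the plants were separate is not given, so p-values measure only the spread between these samples. Precision is limited by the number of arrays.

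The 2 N22 arrays stood apart from the other 10. Their 75th percentiles of processed signal were 15.7 and 16.2, against 2310 to 4800, and 41.2% and 39.3% of their probes were well above background, against 74.0% to 79.5%. Across probes they correlated with the other arrays at 0.182 to 0.269 before stress and at 0.106 to 0.187 at 8 days, while the other 10 correlated with each other at 0.76 to 0.977. The scanner software marked both for evaluation and the others as in range. The brightest N22 probes included those of the photosystem II D1 protein (Os04g0473150, signals 71100 and 70800) and elongation factor EF-TuA (Os02g0595700, 67000 and 63800). These lie near the top of the scale, where 31 and 29 N22 probes were saturated against 667 to 1050 elsewhere, so their levels are not compared with the other arrays. Ratios between the N22 arrays are given below, and many of them rest on probes near background.

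**Figure D1:**
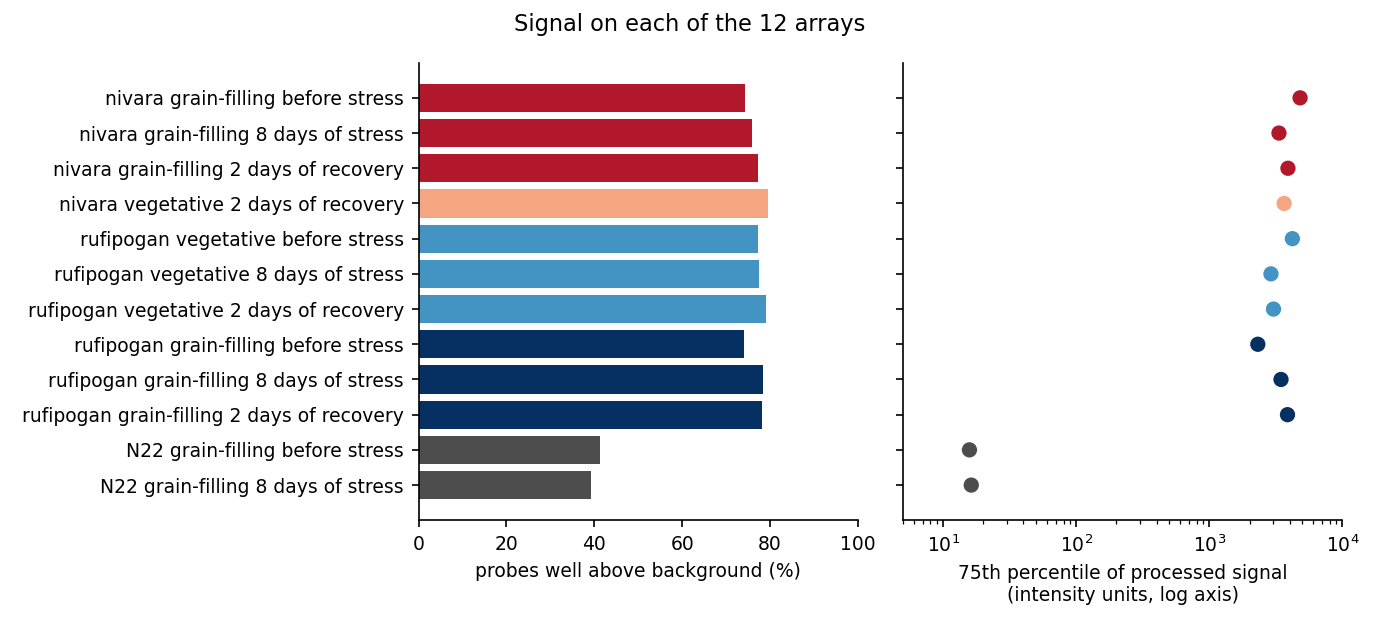
Bars show the percent of probes well above background and points the 75th percentile of processed signal (intensity units, log axis) on each of the 12 arrays. The 2 N22 arrays are lowest in both, with 41.2% and 39.3% of probes and 75th percentiles of 15.7 and 16.2.

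After 8 days of stress, genes of late embryogenesis abundant proteins and dehydrins, which accumulate in drying tissue, were higher than before stress in 21 of 23 measured members, with a median log2 change of 3.49 over 4 plant types (camera adjusted p = 7.66e-08, and adjusted p = 0.602 with an estimated correlation). The dehydrin DHN1 (Os11g0451700), well above background on 2 of 4 arrays before stress, was at least 74.2-fold higher in the mean. By pair its bound was log2 14.23 in nivara, 6.46 and 3.08 in rufipogan vegetative and grain-filling, and 1.09 in N22. The dehydrin RAB21 (Os11g0454300) was higher by 4.62 ± 1.37 (SE, n = 4 pairs) and Os04g0589800 by 4.71 ± 1.29. The list's median was 8.46 in nivara grain-filling, 2.57 in rufipogan vegetative, 0.82 in rufipogan grain-filling and 0.03 in N22. Raising dim members to their array's lowest signal well above background left these medians unchanged, at 353-fold, 5.94-fold, 1.77-fold and 1.02-fold. These folds are therefore no more cautious than the log2 medians. In nivara 14 members were well above background before stress and 23 at stress, and in N22 13 at both times. Without the nivara grain-filling plant the list's median was 1.37, and under normexp correction 2.02.

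Genes of the chloroplast were lower at stress. Light harvesting and photosystem genes were lower in 37 of 42, with a median of −1.07 (camera adjusted p = 4.04e-08, and adjusted p = 0.602 with an estimated correlation), chlorophyll synthesis genes in 17 of 19, with −1.30 (7.66e-08 and 0.602), and chloroplast ribosomal proteins in 21 of 23, with −1.38 (3.06e-07 and 0.602). CP24 (Os04g0457000), a light-harvesting protein, was lower by log2 −3.28 ± 0.87, a photosystem I subunit (Os05g0242400) by −1.90, a magnesium chelatase subunit (Os03g0563300) by −2.35 and PORB (Os10g0496900), a protochlorophyllide reductase, by −1.47. The light harvesting median was −2.04 in nivara, −0.78 in rufipogan grain-filling and −0.98 in N22, and 0.35 in rufipogan vegetative, where the chloroplast ribosomal median was 0.081. Without the nivara grain-filling plant the medians of these 3 lists were −0.56, −0.86 and −0.60, and under normexp correction −0.67, −1.14 and −1.10. Calvin cycle genes were lower in 21 of 27, with −0.36 (0.00667 and 0.639; −0.70 without N22 and −0.59 under quantile normalization), with phosphoribulokinase (Os02g0698000) at −2.21.

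Abscisic acid signalling genes, of the main drought hormone, were higher in 22 of 30, with a median of 0.57 (camera adjusted p = 0.00667, and adjusted p = 0.602 with an estimated correlation). The phosphatase PP2C51 (Os05g0572700) was higher by log2 5.28 in the mean. It was well above background on 1 of 4 arrays before stress and 3 of 4 at stress, so this is no lower bound. By pair, with dim arrays at their bound, it was at log2 13.87 in nivara, 4.55 and 3.11 in rufipogan vegetative and grain-filling, and −0.40 in N22. The phosphatase PP2C30 (Os03g0268600) was higher by 1.98 ± 0.568, bZIP72 by 1.23, SAPK3 by 1.02 and TRAB1 by 0.98. Under quantile normalization the list had an adjusted p of 0.0747, in a range of 0.00067 to 0.602 over the alternatives. Pathogenesis-related genes were higher in 64 of 93, with 0.40 (0.00654 and 0.639). Their median was 0.94 in nivara and 0.99 in rufipogan vegetative, 0.07 in N22 and −0.56 in rufipogan grain-filling, where 34 members were at least 2-fold lower and 20 higher. Starch and sucrose genes were higher in 36 of 53, with 0.37 (0.00654 and 0.602; 0.18 under normexp correction). Without the nivara grain-filling plant the calls of these 3 lists ended, at adjusted p = 0.0926, 0.175 and 0.109; over the alternatives the last 2 ranged from 0.00155 to 0.639 and from 0.00642 to 0.602. Flowering time genes were lower in 7 of 7, with −0.94 (0.00352 and 0.461; −0.48 under normexp correction), with MADS14 at −2.29.

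These were the 9 of 27 lists called at stress; in each, 0 members passed over all genes and 0 adjusted over the list alone. Of 11 drought transcription factors 1 rose when adjusted over the list alone, NAC10, and 0 over all genes, and the list was not called (0.331). DREB1B was at −1.50, DREB2A at 1.01, HsfA2c at 0.33 and SNAC2 at 0.32. Among root-enriched genes HKT2;1 was at 1.75, Lsi1 at 1.39 and RCc3 at 1.94. RCc3 was well above background on 3 of 4 arrays at stress and 0 of 4 before, so its size is uncertain. With dim arrays at their bound, RCc3 was at log2 4.43 in nivara, 0.54 and 1.16 in rufipogan vegetative and grain-filling, and 1.33 in N22. For Lsi1 the same measure was −1.33 in N22, against 2.03 to 2.80 in the other plant types. Among senescence genes, the chlorophyll breakdown enzyme PAO was at 1.44, RCCR1 at 0.88 and NYC3 at 0.23. Floral organ genes, markers of panicle tissue, were not called (0.775), although MADS3 rose by 1.86 when adjusted over the list alone. Seed storage genes, a list meant to mark grain, were not called (0.253) and had a median of 0.30, with 1.85 in nivara. Only 6 of its 24 members are described as glutelins, prolamins or globulins, so the list is mixed. The clock list, a sign of the time of day, was not called (0.331), with TOC1 at −1.56 and LHY at 1.27. The list test looks for a shift in 1 direction and can miss members that move opposite ways. A difference in sampling hour therefore stays open. In the antioxidant, floral organ, jasmonate, wax and cell wall expansion lists, the median, mean and test differed in sign.

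Gene by gene, limma called 0 of 35430 probes at stress (smallest adjusted p = 0.64), with 2496 at an unadjusted p under 0.05 where chance gives 1772. The genes named here therefore did not pass. NAC10 (Os11g0126900, probe at chromosome 11, 1217672 to 1217731), a transcription factor, was higher by 4.02 ± 0.908, with 7.41 in nivara, 2.05 and 5.02 in rufipogan vegetative and grain-filling, and 1.60 in N22. A cytochrome P450 (Os02g0569900, chromosome 2, 22568898 to 22568957) was higher by 2.59 in nivara, 2.61 and 2.15 in rufipogan vegetative and grain-filling, and 1.04 in N22. Release factor eRF1 (Os05g0373900) was higher by 3.34 ± 0.667, a tau glutathione S-transferase (Os10g0527800) by 2.91 ± 0.6 and NADH-dependent glutamate synthase (Os04g0490000) by 2.12, while a cupredoxin (Os03g0115000) was at least 6.41-fold higher. Cinnamyl alcohol dehydrogenase (Os09g0400400), of lignin synthesis, was at least 8.02-fold lower. Annexin RJ4 (Os05g0382600) was at −2.25 ± 0.423, a pectin methylesterase (Os07g0691100) at −1.89, argonaute 4 (Os02g0169400) at −1.83 and a potassium channel (Os01g0175100) at −1.82. Each of the 4 stress pairs lies within 1 slide, and without N22 the genes of this paragraph had an adjusted p of 0.515.

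**Figure D2:**
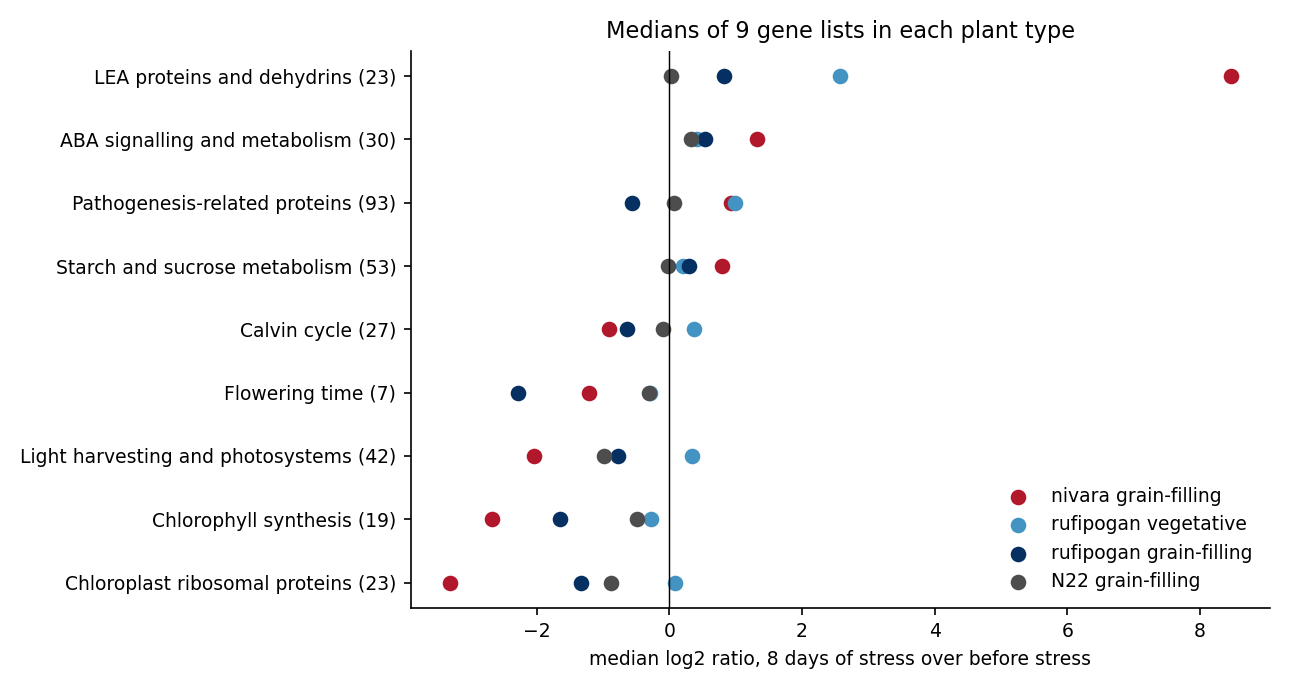
Points show the median log2 ratio of 8 days of stress over before stress for the 9 called gene lists (number of members in brackets) in each of 4 plant types. The late embryogenesis list runs from 0.03 in N22 to 8.46 in nivara, and 5 lists have medians on both sides of 0.

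**Figure D3:**
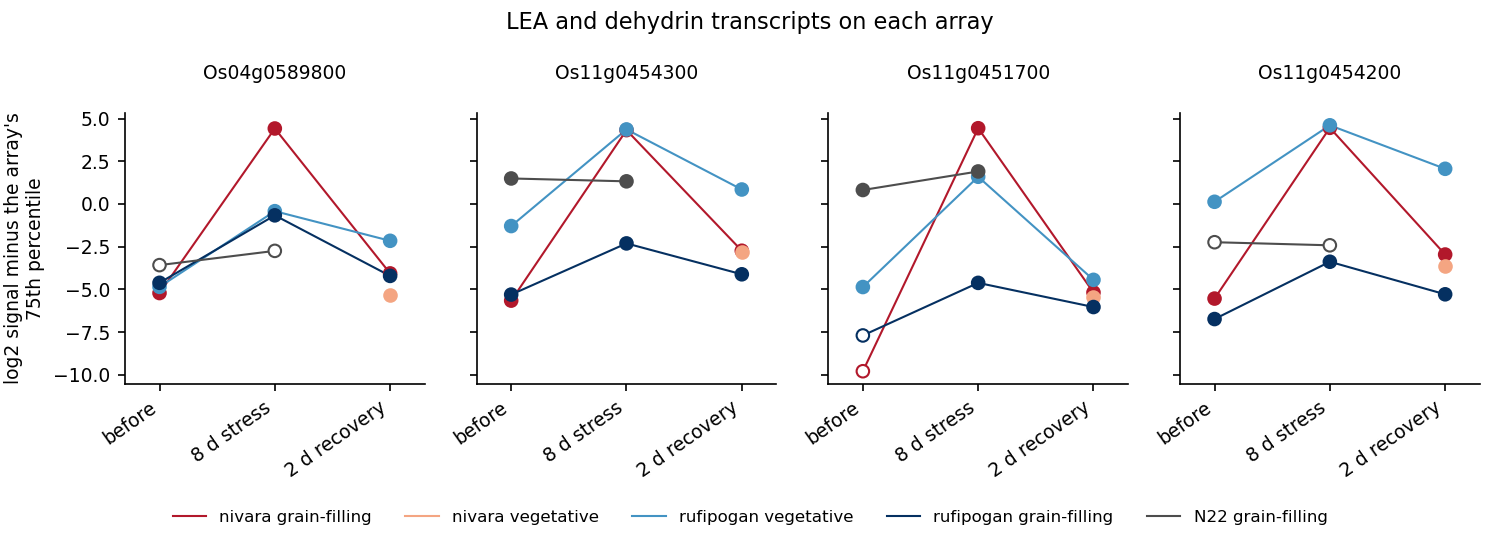
Points show log2 signal minus the array's 75th percentile for 4 late embryogenesis and dehydrin genes at each time, with lines joining the arrays of a plant type and open points not well above background. Nivara is higher at stress than before for all 4, with DHN1 near background before stress, and N22 differs by −0.18 to 1.09, with open points for 2 of the genes.

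Recovery against stress asks what returned within 2 days, in the 3 plant types with both times. The late embryogenesis genes were lower in 22 of 23, with a median log2 change of −3.19 (camera adjusted p = 1.2e-09, and adjusted p = 0.453 with an estimated correlation), and with −7.06 in nivara, −2.29 in rufipogan vegetative and −1.69 in rufipogan grain-filling. Light harvesting genes were higher in 37 of 42, with 1.16 (1.2e-09 and 0.453), chlorophyll synthesis genes in 17 of 19, with 1.63 (1.58e-09 and 0.453), and chloroplast ribosomal proteins in 21 of 23, with 1.52 (3.27e-08 and 0.453). A Rubisco small chain (Os12g0291200) was higher by 3.97, CP24 by 3.40 and magnesium chelatase subunit H (Os03g0323200) by 2.65, while PP2C51 was at −4.92 and PP2C30 at −1.82. Without the nivara grain-filling plant the medians were −1.54, 0.35, 0.73 and 0.47 in the order of these lists, and the stress arrays are shared with the comparison of stress with before.

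Abscisic acid signalling genes were lower in 25 of 30, with −0.68 (0.00128, and adjusted p = 0.453 with an estimated correlation). Their median was −0.20 without nivara grain-filling. Calvin cycle genes were higher in 23 of 27, with 0.60 (0.00128 and 0.499, with 0.467 under normexp correction and 5.06e-05 to 0.499 over the alternatives). The Calvin cycle call ended without nivara grain-filling (camera adjusted p = 0.0514). Heat shock proteins were lower in 46 of 68, with −0.21 (0.00717 and 0.453). Seed storage genes were lower in 19 of 24, with −0.54 (0.0128 and 0.515). Their call ended without nivara grain-filling (median −0.20, adjusted p = 0.217) and under normexp correction (median 0.29, with 0.44 for all probes, adjusted p = 0.131), in a range of 0.00481 to 0.562 over the alternatives. In these 8 lists 0 members passed. limma called 0 probes, with 1643 at an unadjusted p under 0.05, below the 1772 that chance gives (smallest adjusted p = 0.786). Cinnamyl alcohol dehydrogenase was higher by 3.01, with 2 of 3 recovery arrays and 0 of 3 stress arrays well above background. A light-harvesting protein (Os01g0720500) was higher by 4.89 ± 1.17 (n = 3 pairs) and a Lon protease (Os07g0509700) by 1.51. A glyoxalase (Os05g0171900) was at −3.23, a copine (Os08g0494300) at −3.36 and a RING protein (Os06g0167200) at −2.64, the last 2 at 0.041 and 0.278 under normexp correction, below the 0.44 of all probes there. In the antioxidant, cell division and floral organ lists the median, mean and test differed in sign. The nivara pair lies within 1 slide but both rufipogan pairs span 2; with the slide as a block 7 lists were called, and abscisic acid (0.0824, in a range of 2.23e-08 to 0.453) and heat shock (0.519, in a range of 4.6e-05 to 0.519) no longer. Medians then moved to −4.38 for late embryogenesis, 1.87 for light harvesting, 2.78 for chlorophyll synthesis, 2.89 for chloroplast ribosomal, 0.99 for Calvin cycle, −0.42 for abscisic acid, −1.34 for seed storage and −0.11 for heat shock genes. Under normexp correction the late embryogenesis median was −2.03 and that of heat shock genes −0.02.

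Recovery against before asks what had not returned. The cytochrome P450 Os02g0569900 was higher by log2 3.45 ± 0.432, with 3.20 in nivara and 3.84 and 3.82 in rufipogan. A carboxypeptidase (Os03g0386800) was higher by 3.47 and a NAC77-like factor (Os11g0127000) by 2.33, each well above background on 1 of 3 arrays before stress, and syn-copalyl diphosphate synthase (Os04g0178300), of phytoalexin synthesis, by 1.99. Annexin RJ4 (Os05g0382600) was at −1.99 and a lysine decarboxylase-like gene (Os03g0109300) at −1.98. In the fit, the late embryogenesis genes had a median of −0.06 and were not called (0.55). That value is no direct mean of the 3 pairs. It also draws on the N22 arrays before and at stress, where the list's median stress ratio was 0.03, and N22 has no array at recovery. By pair the list's median was 0.73 in nivara, 0.29 in rufipogan vegetative and −0.52 in rufipogan grain-filling. Under normexp correction the fitted median was 0.88, where the median of all probes was 0.34. These genes did not pass: limma called 0 probes, with 646 at an unadjusted p under 0.05, below the 1772 that chance gives (smallest adjusted p = 1).

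Starch and sucrose genes were higher in 37 of 53, with a median of 0.35 (camera adjusted p = 0.0168, and adjusted p = 0.808 with an estimated correlation), with sucrose synthase (Os03g0401300) at 1.11. Jasmonate genes were lower in 24 of 33, with −0.30 (0.0374 and 0.917), and with 0.35 in nivara, 0.03 in rufipogan vegetative and −1.76 in rufipogan grain-filling; a lipoxygenase (Os12g0560100) was at −1.46 and allene oxide synthase (Os03g0225900) at 2.31. Heat shock proteins were lower in 41 of 68, with −0.12 (0.0484 and 0.808), and had a median of 0.12 under normexp correction, below the 0.34 of all probes there. The starch call ended without nivara grain-filling (0.078) and under normexp correction (0.414), in a range of 0.00647 to 0.948 over the alternatives. The heat shock call ended without N22 (0.179) and under quantile normalization (0.115), in a range of 0.00457 to 0.948. The jasmonate call ended under quantile normalization (0.0652, in a range of 7.19e-06 to 0.948), and the jasmonate median was −0.84 without nivara grain-filling. With the slide as a block 0 of these 3 calls were kept, and the jasmonate median was 0.50. In the clock, late embryogenesis, floral organ, cell wall expansion, nitrogen remobilisation, photorespiration and cytosolic ribosomal lists, the median, mean and test differed in sign.

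The stage comparison asks how vegetative leaves of rufipogan differ from those at grain-filling, at the same 3 times. The pairs are times of the same 2 plant types, so neither stage is replicated. An FtsH protease gene (Os06g0229000, probe at chromosome 6, 6700283 to 6700342) was at least 891-fold higher in vegetative leaves (n = 3 pairs, adjusted p = 0.00136, well above background on 2 of 3 grain-filling arrays). A monosaccharide transporter (Os07g0131600) was at least 473-fold higher (0.000782), peroxidase P7 (Os06g0547400) at least 382-fold (0.0205) and Phi-1 (Os06g0220000) at least 306-fold (0.00636). An ankyrin repeat gene (Os05g0124000) was at least 490-fold lower (0.000702), a molecular chaperone of the Hsp40 type (Os06g0474800) fell by 7.23 (0.0142) and a leucine-rich repeat gene (Os11g0558900) fell by 6.22 (0.0155). Hd1 (Os06g0275000), a photoperiod regulator of heading, fell by 3.58 ± 0.672 (0.0293). The clock list was not called (0.616), but 1 of its 7 members rose over all genes, LHY by 4.83 (0.0201), and 2 rose and 2 fell adjusted over the list alone. A difference in sampling hour between the stages stays open too.

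Pathogenesis-related genes were higher in vegetative leaves in 78 of 93, with a median of 1.30 (camera adjusted p = 1.04e-06, and adjusted p = 0.658 with an estimated correlation); 6 rose and 1 fell over all genes, 12 and 1 adjusted over the list alone, with PR-1 (Os02g0786900) at least 14.8-fold higher (0.00592) and a beta-1,3-glucanase (Os05g0535100) the 1 that fell (−3.54). Heat shock proteins were higher in 49 of 68, with 0.79 (0.000101 and 0.492); 18 rose adjusted over the list alone and 5 over all genes, namely Hsp20 genes Os10g0159700, at least 33.0-fold (0.0257), and Os01g0588000, at least 18.6-fold (0.0484), Hsp70 genes Os03g0218500 at 4.48 (0.0443) and Os11g0696600 at 3.48 (0.0471), and ClpB (Os02g0181900) at 2.49 (0.0339; 0.0597 without N22). Cell wall expansion genes were higher in 35 of 50, with 1.17 (0.000849 and 0.658); 8 rose and 2 fell over all genes, 10 and 3 adjusted over the list alone, with the expansin EXPA5 (Os02g0744200) at 5.07 (0.0082), EXPA16 (Os06g0621900) at −2.39 and cellulose synthase-like A5 (Os03g0377700) at −1.96. Aquaporins were higher in 14 of 17, with 0.83 (0.0259 and 0.662); 1 rose over all genes, a TIP1-2-like tonoplast channel (Os01g0975900) at 4.33, and 5 rose and 1 fell adjusted over the list alone. Late embryogenesis genes were higher in 19 of 23, with 1.48 (0.0148 and 0.736), with RAB16B (Os11g0454200) up by 7.40 ± 1.58 (0.0422), and starch and sucrose genes in 34 of 53, with 0.40 (0.0365 and 0.662), with sucrose synthase (Os03g0401300) up by 3.26 (0.0138); 1 member rose in each, by either count. Jasmonate genes were higher in 26 of 33, with 0.72 (0.0391 and 0.736), and 0 passed by either count.

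Cytosolic ribosomal proteins were lower in vegetative leaves in 135 of 140, with a median of −0.51 (1.04e-06, and adjusted p = 0.736 with an estimated correlation); 1 fell over all genes and 0 adjusted over the list alone, the 60S protein P0 (Os11g0135400) at −2.01 (0.0367; 0.0647 without N22). Flowering time genes were lower in 6 of 7, with −1.51 (0.0259 and 0.492; 0.0658 under quantile normalization and 0.0177 to 0.492 over the alternatives), and Hd1 fell by either count. MADS14 was at −3.54 (0.128), MADS15 at −1.18 (0.261), MADS18 at −0.49 (0.52) and MADS50 at 0.13 (0.913), and Ehd1 was at −1.51 (0.341). By time, with dim arrays at their bound, Ehd1 was at log2 −3.73 before stress, −0.46 at stress and −0.34 at recovery. Ehd1 was well above background on 1 of 3 grain-filling arrays and 0 vegetative ones, so its size is uncertain. Cell division genes were not called (0.273); 2 rose and 4 fell over all genes, 3 and 6 adjusted over the list alone. PCNA was at −2.99 (0.0175) and a histone H2A (Os08g0427700) at −3.62 (0.0182), while the cyclin Os03g0225200 was at least 14.6-fold higher (0.0244) and Os05g0325200 rose by 1.96 (0.0421). Abscisic acid signalling genes were not called (0.606); 1 rose and 3 fell by either count. The kinases SAPK9 and SAPK10 were at −3.92 (0.0185) and −2.26 (0.0347) and the phosphatase PP2C08 at −2.89 (0.02), while PP2C49 (Os05g0457200) rose by 2.82 (0.0436). Seed storage genes, the mixed list meant to mark grain, were higher in 19 of 24 and not called (0.0613). Over all genes 1 rose, Os05g0160300 at 4.71, and 3 rose adjusted over the list alone. Os05g0160300 is described by a lipid transfer and seed storage domain, which does not make it a marker of grain. Floral organ genes were not called (0.291); 0 passed over all genes and 1 fell adjusted over the list alone, with MADS1 (Os03g0215400) at least 24.8-fold lower. Under normexp correction the medians of pathogenesis-related, cell wall expansion, late embryogenesis and flowering time genes were 0.71, 0.40, 0.82 and −0.998. In the drought transcription factor and photorespiration lists the median, mean and test differed in sign.

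limma called 1553 probes in the stage comparison (smallest adjusted p = 7.95e-05), 1094 higher and 459 lower in vegetative leaves, for 675 and 319 genes. Each pair lies within 1 slide, and 1305 were called with the slide as a block. Calls numbered 828 without the 2 N22 arrays (799 shared), 760 under quantile normalization, 320 under normexp correction and 244 among probes well above background on all 12 arrays. They numbered 423, 206 and 142 without rufipogan vegetative before stress, at stress and at recovery, and 155 and 409 without rufipogan grain-filling at stress and at recovery.

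**Figure D4:**
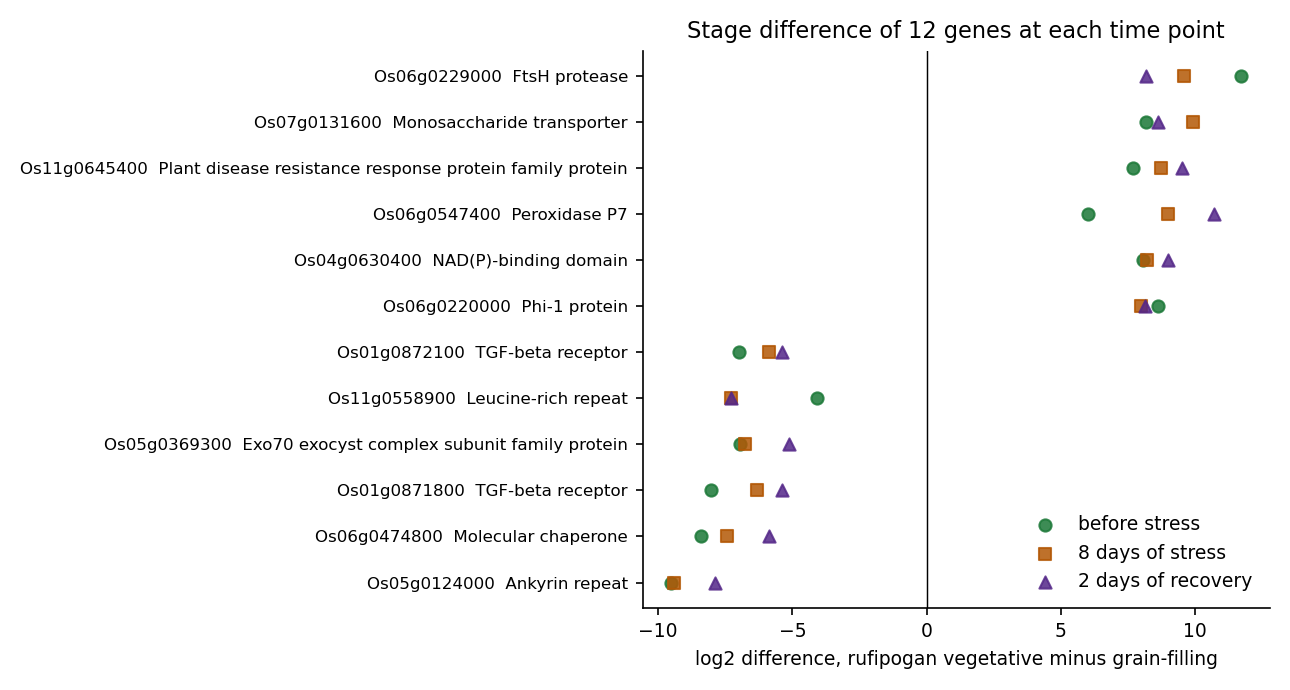
Points show the log2 difference, vegetative minus grain-filling rufipogan, of the 12 named genes at each of the 3 times. All 3 times lie on the same side of 0 for each gene. For genes near background in 1 stage, such as FtsH in grain-filling leaves before stress, the size of the difference is uncertain.

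Rufipogan against nivara at grain-filling asks how the wild genotypes differ. Here too the pairs are times of 2 plant types, so neither genotype is replicated. Histone H2B (Os01g0152700) was at least 2680-fold higher in rufipogan (n = 3 pairs, adjusted p = 0.000197) and an RNA polymerase gene annotated RPB17 (Os03g0845700) at least 498-fold (4.85e-05), each well above background on 1 of 3 nivara grain-filling arrays. The nivara vegetative array, outside this comparison, read 22100 and 5070 for these 2 genes, so neither was absent from nivara. A FAR1 gene (Os03g0843700) was at least 392-fold higher (7.9e-05) and a bHLH factor (Os04g0631600) at least 383-fold (0.000284). The monosaccharide transporter Os07g0131600 was at least 528-fold lower (0.000376), 5-formyltetrahydrofolate cyclo-ligase (Os12g0168000) at least 237-fold (0.00155) and an agglutinin (Os10g0462600) at least 111-fold (0.00748). The transporter was also at least 473-fold higher in vegetative than in grain-filling rufipogan, on the same 3 grain-filling arrays. Grain-filling rufipogan was thus apart from both vegetative rufipogan and grain-filling nivara. The same held for 54 of the 60 genes past the threshold in both comparisons. Those arrays enter the 2 comparisons with opposite signs, which favours such differences in advance. Such differences need not be ones of the genotype.

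limma called 734 probes between rufipogan and nivara (smallest adjusted p = 3.7e-05), 586 higher and 148 lower in rufipogan, for 421 and 94 genes. The 2 genotypes share no slide, so genotype and slide cannot be told apart. The share of higher calls was 79.8%, against 68.3% of 139 under quantile normalization and 40.9% of 22 under normexp correction, where the median of all probes went from 0.13 to −0.30. Calls numbered 5 among probes well above background on all 12 arrays (Os02g0216300, Os05g0404400, Os06g0479400, Os07g0294300 and Os10g0459900), 294 with a variance trend, 41 with the 6 arrays alone and 299 without N22 (297 shared). Calls numbered 344 and 134 without nivara before stress and at recovery, and 140 and 141 without rufipogan at stress and at recovery.

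N22 against the wild plants at grain-filling asks how the cultivar differs. A glyoxalase (Os01g0173600) was at 14.16 and a beta-galactosidase (Os03g0165400) at 13.93, while NYC1 (Os01g0227100), of chlorophyll breakdown, was at −5.66 and a RING protein (Os02g0682300) at least 94.4-fold lower. limma called 24781 probes (smallest adjusted p = 2.35e-06), 14237 higher and 10544 lower in N22, for 10135 and 6167 genes. The N22 values are relative to a 75th percentile near 16.2, close to background, so they are not read as fold changes of leaf transcripts, and N22 shares no slide with the wild arrays at these times. The share of higher calls was 57.5%, against 39.2% of 26000 under quantile normalization and 79.6% of 24943 under normexp correction.

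A different stress response was tested last. In nivara grain-filling 56.5% of probes differed at least 2-fold between stress and before, in rufipogan grain-filling 36.1%, in rufipogan vegetative 19.6% and in N22 21.5%. Under quantile normalization the N22 number went from 7599 to 15315 probes and then lay above the 11814 of rufipogan grain-filling. The log2 ratios correlated across probes, which are not independent replicates, at 0.281 between nivara and rufipogan vegetative, 0.241 between nivara and rufipogan grain-filling, 0.115 between the rufipogan stages and −0.0613 to 0.0353 between N22 and the others. limma called 0 probes for N22 against the wild plants, with 1046 at an unadjusted p under 0.05, and 0 for vegetative against grain-filling, with 448, each with a smallest adjusted p of 1. On simulated data the N22 test recovered 0% of changes at every size tried.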

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

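All tests of the N22 arrays, and those of a poor array and of the stress itself for nivara, were chosen after the result was seen; the others here were written before.

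The 2 N22 arrays lay far from the other arrays of their times in the percent of probes well above background (41.2 and 39.3) and in the log2 75th percentile of signal (3.97 and 4.02). Less labelled leaf RNA alone is argued against by the rank correlation with the other grain-filling plants, 0.0923 at most over 11052 probes, against 0.941 and 0.85 between nivara and rufipogan before stress and at stress. For complete replacement of the leaf RNA, 100% of the 200 probes brightest elsewhere were well above background. On the N22 arrays 32.5% and 32.7% of the spots of random or artificial sequence were so too, against 10% to 25.2% elsewhere. The flag thus also passes nonspecific signal, and the test does not decide this. A name for this explanation that covered more was narrowed after the 100% was seen. The genotype as the whole account is argued against by the signal of those 200 probes, 0.192% of that elsewhere at most. This test replaced a first one (81.4% and 59.3% of 140 cytosolic ribosomal genes well above background) that had decided nothing. A trace of leaf RNA with nonspecific signal was not tested and stays open, with signal tied to probe GC at 0.453 and 0.472 against −0.0587 to −0.0161 elsewhere.

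The rufipogan stages differed by very large folds at all 3 times. Of 994 genes past the threshold 282 had another tested probe. In 95% of these at least 1 such probe differed at least 2-fold the same way. For them a base difference under single probes is argued against, while the other genes had 1 tested probe and could not be examined. Growth stage could not be decided: 71% of the genes went the same way between the nivara stages at recovery, where 53.2% of all genes did. Different accessions behind the stages remain a candidate explanation, as neighbouring genes past the threshold in 1 direction were 2.49 times as frequent as in shuffled orders (56 pairs, against at most 37 in 1000 shuffles). Co-regulated neighbours could give the same and were not tested.

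The nivara grain-filling plant moved most at stress. A poor array is argued against by its 75.9% of probes well above background, within the range of the others. Grain tissue as a large share of the sample is argued against by 6 storage genes with a median signal percentile of 48.1 there. This was still the highest of the 12 arrays (35.8 before stress, others 33.3 to 44.9), so a small share stays open. The wider seed storage list was at 1.85, but it is mixed. For the stress itself, 8.63% of the log2 rise of the late embryogenesis genes was left at recovery, but rise and return share that 1 stress array, so this decides nothing. The stress, plant-to-plant variation and other faults of the sample all stay open.

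In nivara at stress the median log2 ratio lay apart from the other plants for cell division (−0.088, others −0.02 to −0.01) and glutathione S-transferases (0.97, others 0.01 to 0.09). These are 2 of 27 groups of list medians tested, where chance gives about 1 in 20; the 4 N22 values are those among 15 groups of array measures. In rufipogan vegetative leaves the medians of the Calvin cycle (0.37), chloroplast ribosomal (0.081) and light harvesting (0.35) lists were above 0 and that of floral organ genes (−1.07) below, with all 3 grain-filling plants on the other side; the differences were not tested, and 1 of the 3 is N22, whose ratios rest in part on background (−0.09 for the Calvin cycle and 0.01 for floral organ genes). A filter on small medians was dropped after the first output, which added the Calvin cycle, chloroplast ribosomal and floral organ lists.

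Splits of the same arrays did not exclude chance for the gene lists. All counts of splits here include the real split. At least the 9 lists called at stress came in 7 of 35 (highest other 12). At least the 8 lists of recovery against stress came in 18 of 35 (12), and the 3 lists of recovery against before in 32 of 35 (13). For probes the real count was 0 in all 3, so 35 of 35 splits reach it by construction and decide nothing (highest others 25, 72 and 41). Among the 8 splits that part as many pairs, as many lists came in 2, 7 and 7, and the splits with 25, 72 and 41 probes part fewer pairs, which points to a structure of plant types. For 3 arrays against 3 the 10 splits are too few for a share under 0.05: for the stages 1 of 10 gave the 1553 probes (highest other 20) and 3 of 10 the 9 lists (13), and for rufipogan against nivara, a split that follows the slide, 1 of 10 gave the 734 probes (3).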

How the results depend on the processing

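Leaving out the 2 N22 arrays, and for gene lists leaving out nivara grain-filling or adding the slide, were chosen after the result was seen. limma called 0 probes between times under every alternative run, with 59 to 4015 at an unadjusted p under 0.05. The stage count of 1553 was 760 under quantile normalization, 320 under normexp correction, 244 among probes well above background on all 12 arrays, 894 with 1 probe per gene, 828 without N22 and 142 to 1156 leaving out 1 array; it was lowest without rufipogan vegetative at recovery (142) or at stress (206), rufipogan grain-filling at stress (155) or recovery (409), and rufipogan vegetative before (423). The rufipogan against nivara count of 734 was 139, 22 and 5 under the first 3 of these, 294 with a trend and robust variances, 41 with only the arrays compared, 299 without N22 and 134 to 1040 leaving out 1 array (344 and 134 without nivara before and at recovery, 140 and 141 without rufipogan at stress and recovery). The N22 count of 24781 was 8154 on all 12 arrays and 16269 with 1 probe per gene. The vegetative stress response had 10 probes with a trend and robust variances, against 0.

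With an estimated correlation, and with fry, 0 lists were called at stress (against 9), recovery against stress (against 8), recovery against before (against 3) and stage (against 9). Lists of recovery against before numbered 1 under quantile normalization, 9 under normexp correction, 8 with the slide as a block, and 1 to 6 leaving out 1 array (1 without rufipogan vegetative before, 5 without nivara before, 6 without rufipogan vegetative at recovery). Stage lists numbered 5 to 12, with 5 without rufipogan vegetative at recovery. N22 probes at least 2-fold at stress were 15315 under quantile normalization, against 7599.

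Normexp correction moved the median of all probes by over 0.1, to 0.44 in recovery against stress, 0.34 in recovery against before and −0.30 in rufipogan against nivara (against 0.13), and turned the sign of 9 named genes: Os11g0180000 (0.46), Os06g0167200 (0.28), Os05g0556400 (0.83), Os08g0494300 (0.041), Os04g0445100 (0.20) and Os07g0216700 (0.53) against stress, and Os05g0574000 (0.89), Os09g0351700 (1.03) and Os01g0135800 (0.44) against before. The cause of these moves was not tested. The slide as a block could not be fitted for rufipogan against nivara or for N22, nor the stress responses without their lone ratio. Signal over background limits most the N22 arrays.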

Other observations

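At recovery the nivara plants of the 2 stages, 1 array each and so without a test, differed at least 2-fold in 38.2% of probes, with 7839 higher and 5693 lower in the vegetative plant. Cell wall expansion genes were higher there, with a median log2 difference of 1.17, as were aquaporins, with 1.32, and cell division genes, with 0.70. Drought transcription factors were lower, with −1.44, WRKY factors with −1.43 and flowering time genes with −1.30. Heat shock (−0.27), jasmonate (−0.82) and late embryogenesis genes (−0.59) were lower in the vegetative nivara plant, while at the same time the lists were higher in vegetative rufipogan (0.94, 2.48 and 2.05, again 1 array each). Cell division genes (−0.23), drought transcription factors (0.86) and WRKY factors (0.26) in rufipogan also went the other way from nivara. Cell wall expansion genes (1.725), aquaporins (0.47) and flowering time genes (−0.68) went the same way.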
